A study of Homo sapiens with 8 samples.

How the data were processed

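The data were gene-level read counts from RNA sequencing of 8 libraries, made from 500 ng of total RNA each with a TruSeq kit per the labels' protocols. The authors deposited 1 table of whole-number counts per gene for all 8 libraries, with no normalization applied to the counts. Per the file headers, the counts were made with featureCounts 1.5.2 from 1 alignment file per library, with gene models of Ensembl release 54 on NCBI build 36. The submitters' processing notes name FastQC 0.10.0, TopHat2 2.0.10, the Subread package, edgeR and the genome build hg18. The recorded counting command sets no strand option, so reads of a gene and of an antisense or overlapping gene cannot be separated. It also sets no option to count reads that map to several places. Such reads, as of close paralogs or processed pseudogenes, were left out, and these genes may be undercounted. Filters on the reads and adapter handling are not given in the sources used here. The table held 33045 gene names and the counts per library ranged from 23722972 to 45970766.

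Each library's line, agent, time and dose came from the labels, and each of the 8 groups held 1 library. LSD1i and vehicle libraries of the same line and time were matched as 4 pairs. That pairing comes from the cell line and the time in the labels, and no replicate numbers pair the libraries. Names were matched to current human gene symbols through a table of current and older symbols: 16725 were current symbols, 3230 were matched through an older symbol (AOF2 is KDM1A, for example) and 13090 had none and were tested but not named. A name can point to another locus than the current symbol does: 115 names lay on another chromosome than the gene now called so, and 361 had exons on more than 1 chromosome. No read was counted on 9387 names. The 11 mitochondrially encoded names matched had 0 reads in all libraries, so that list could not be tested. No name matched RPTOR or RICTOR, which were not analysed here. Coordinates are those of the deposited table, NCBI36, 1-based.

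The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM normalization and filterByExpr at a minimum count of 10, which left 16060 genes over the 8 libraries. The fit had a term for each of the 4 pairs and an LSD1i coefficient for each line, leaving 2 residual degrees of freedom shared by both lines (3 for a single coefficient over all pairs). The difference of response was the contrast of the line coefficients. The vehicle libraries of the lines were compared in a fit of their own with 2 residual degrees of freedom and 15456 genes. P-values were adjusted by Benjamini and Hochberg at 0.05. The common dispersion was 0.0115. With these few residual degrees of freedom the test leans on the spread shared across genes (median prior degrees of freedom 15.6).

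Single pairs had 1 library per agent, so no p-value was computed for them. The log2 ratio was taken from TMM-scaled CPM with a prior count of 2, with an exact conditional binomial 95% interval. These intervals and the floors cover counting error only, since reads without molecular identifiers are not independent molecules. Genes were counted as 2-fold apart at a mean of at least 2 CPM when that interval excluded equality. In a group with no reads over its 2 libraries a fold was bounded against a floor of 3 reads over the group, and with 1 to 3 reads the ratio of summed reads was given with its counting interval.

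Before the data were examined 24 gene lists of 945 members were fixed, of which 910 matched names in the table: LSD1 and its corepressor partners, monocyte and macrophage maturation, neutrophil and eosinophil granule proteins, stem and progenitor genes, erythroid and megakaryocyte genes, lymphoid and mast cell markers, mTOR complexes and regulators, insulin, PI3K and AKT inputs, ATF4 targets, SREBP targets, glycolysis and hypoxia-inducible genes, lysosome and autophagy genes, ribosomal proteins and translation factors, ribosome biogenesis and MYC targets, S phase, G2 and mitosis, type I interferon response, antigen presentation, cytokines and NF-kB targets, ERK feedback, cell death regulators, heat shock and unfolded protein response, replication-dependent histones, and mitochondrially encoded genes. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over the lists. Per pair, a list's median was placed among 10000 random lists of its size matched on expression, as a description. The genes named were also chosen by a rule fixed then: a set of 18 genes whatever their values, the 8 largest rises and 8 largest falls of each line and of the difference among called genes with an average log2 CPM of at least 1 (within a line, with the same direction in both pairs), the 5 highest and 5 lowest of each pair, and up to 4 members of each list discussed. Some genes that this rule names are not reported here. Genes of the chromosome 1 stretch were chosen after their values were seen. The search along chromosomes took autosomal genes with an average log2 CPM of at least 2.

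Every script that tests many genes was tested on simulated counts. Of simulated changes of 1 on the log2 scale, 60.7% were called in KASUMI-1 (15881 genes), 68.5% in THP-1 (15873 genes), 46.1% for the difference (15881 genes), 82.0% over the 4 pairs (15888 genes) and 74.2% between vehicle libraries (15347 genes). Of changes of 2 the shares were 87.4%, 87.4%, 73.9%, 97.3% and 93.7%. A simulated change was equal in all the libraries it was put into, so it did not change with time. A response that grows with time adds to the measured spread and is less likely to be called. These shares therefore do not hold for such responses. In data with no change in a line 0 genes were called there, and 0 lists were called in unchanged data. The simulated genes varied independently of each other. In the data the estimated correlation between members was 0.80 for the ribosomal protein list in KASUMI-1. So the simulation could not show false list calls that arise when members vary together. Alternatives were RLE normalization, no filter on low counts, DESeq2 1.42.0, limma-voom, no pair block, fits of a line's libraries alone, leaving out each pair in turn, other prior counts and count minimums for the pairs, and for lists camera with an estimated correlation and fry. Scaling by library size alone was planned for the single pairs and added after the data were seen for the gene calls.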

Results

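Messenger RNA was sequenced from a pair of acute myeloid leukemia lines treated with DDP38003, an inhibitor of the histone demethylase LSD1 (gene KDM1A), at 0.5 µM, or with vehicle. KASUMI-1, a line that carries the RUNX1::RUNX1T1 fusion, was labelled sensitive to LSD1 inhibition and was sampled at 6 and 72 h. THP-1, a monocytic line with a KMT2A fusion, was labelled resistant and was sampled at 24 and 72 h. The times were chosen by the study in each line as the first that showed, and the last that was tested for, a secondary effect of the inhibitor on the kinase mTOR. Each of the 8 combinations of line, agent and time was 1 library, so each line had 2 matched pairs of LSD1i and vehicle libraries. Counted reads per library were 41200025 (KASUMI-1 vehicle 6 h), 39385565 (KASUMI-1 LSD1i 6 h), 23722972 (KASUMI-1 vehicle 72 h), 45970766 (KASUMI-1 LSD1i 72 h), 43392502 (THP-1 vehicle 24 h), 42623571 (THP-1 LSD1i 24 h), 38199393 (THP-1 vehicle 72 h) and 35131884 (THP-1 LSD1i 72 h). No label says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and that spread also holds any change of the response with time. Values after ± are approximate standard errors, taken as the size of the fitted value divided by the square root of its F statistic. They are rough for genes with few reads. They lean on a spread shared across genes and libraries and do not show how far the 2 pairs of a line lie apart.

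The first comparison asked which transcripts the inhibitor changed in the sensitive line. In KASUMI-1 GIMAP4, a GTPase of lymphoid cells, went from 3 reads in the vehicle libraries together to 968 in the LSD1i libraries, a ratio of 243 with a 95% counting interval of 83.0 to 1181. CD86, the co-stimulatory ligand of antigen-presenting cells, rose by 4.16 ± 0.26 on the log2 scale (adjusted p = 2.22e-08, edgeR's quasi-likelihood test). LY96, the partner of Toll-like receptor TLR4, rose by 4.68 ± 0.43 and lysozyme (LYZ), a secreted product of myeloid cells, by 2.82 ± 0.35. The integrin chain ITGAM (CD11b) rose by 1.36 ± 0.29 (1.06 without the 72 h pair, adjusted p = 0.127) and CSF1R, the receptor of the macrophage growth factor, by 1.04 ± 0.16.

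Other large rises in KASUMI-1 were those of CAMSAP2, which binds microtubule minus ends (4.37 ± 0.33), FCRLA, an Fc receptor-like protein (a ratio of 65.3, interval 22.1 to 319), the prolactin receptor PRLR (42.2, interval 7.27 to 1696) and the nuclear body protein SP140 (23.0, interval 6.10 to 194). BHLHE22, a bHLH transcription factor, had 0 reads in the vehicle and 13 in the LSD1i libraries, at least 3.27-fold higher against a floor of 3 reads over the vehicle pair. Among genes with an average log2 CPM of at least 1 the largest falls were these. The surrogate light chain gene IGLL1 changed by -1.88 ± 0.35, the metallothionein MT2A by -1.38 ± 0.25, RAB3IL1 by -1.35 ± 0.36, the Nogo receptor RTN4R by -1.33 ± 0.20, HES6 by -1.21 ± 0.21 and syndecan SDC1 by -1.21 ± 0.20. The fucosyltransferase FUT7 went from 12 to 2 reads, a ratio of 0.126 (0.0137 to 0.564), and RAB11FIP5 from 6 to 0, at least 2.65-fold lower. In all, 1128 genes rose and 817 fell among 16060 tested by edgeR's quasi-likelihood test at a Benjamini-Hochberg threshold of 0.05, of which 319 and 34 moved at least 2-fold. The share of rises, 58.0%, was 49.8% with RLE normalization and 44.9% with DESeq2. Which direction held more genes thus depended on the method. The 72 h pair and the pairing carried much of this count: 306 genes were called without the 72 h pair, 1238 without the THP-1 24 h pair that shares the spread estimate, and 100 without the pair block. Of 96 called genes chosen for naming, the calls of 67 ended without the 72 h pair, of 26 without the THP-1 24 h pair, of 19 without the THP-1 72 h pair and of 6 without the 6 h pair. The fitted value of FCRLA was 3.71 without the 72 h pair and 10.69 without the 6 h pair, against 5.61 over both, and that of SP140 was 7.79 without the 6 h pair, against 4.445. IGLL1 stood at -0.71 without the 72 h pair and at -3.15 without the 6 h pair. MT2A stood at -0.63 (adjusted p = 0.0599) and -2.21, and RAB3IL1 lost its call without the 6 h pair (-0.79, adjusted p = 0.313) and without the THP-1 24 h pair (0.0510). The calls of FUT7, RAB11FIP5 and BHLHE22 ended without the 72 h pair (adjusted p = 0.372, 0.667 and 0.131). That of BHLHE22 also ended without the 6 h pair (0.0705) and that of FUT7 also without either THP-1 pair (0.0640 at 24 h and 0.0598 at 72 h).

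Gene lists fixed before the data were examined were then tested in KASUMI-1. Of 52 ribosome biogenesis and MYC target genes 15 fell and 1 rose, and adjusted over the list alone 23 fell and 1 rose (limma camera adjusted p = 7.58e-10, and adjusted p = 0.739 with an estimated correlation). The nucleolar proteins NOP16, RRP9 and MRTO4 fell by 0.68 ± 0.12, 0.68 ± 0.15 and 0.65 ± 0.12, while POLR3G, a subunit of RNA polymerase III, rose by 0.64 ± 0.14. MYC itself fell by 0.42 ± 0.13, a call lost without any 1 of the 4 pairs (adjusted p = 0.0766 to 0.188). Of 40 S phase and DNA replication genes 10 fell and none rose, and adjusted over the list alone 13 fell (camera adjusted p = 6.53e-08, and adjusted p = 0.739 with an estimated correlation). Among them were the flap nuclease FEN1 (-0.61 ± 0.14), thymidine kinase TK1 (-0.57 ± 0.16), the helicase subunit MCM7 (-0.52 ± 0.16) and the replication origin factor CDC45 (-0.50 ± 0.15). Of 39 cholesterol and fatty acid synthesis genes under SREBP control 11 fell and none rose, and adjusted over the list alone 16 fell (camera adjusted p = 2.65e-07, and adjusted p = 0.739 with an estimated correlation). They included the sterol enzyme MVD (-0.79 ± 0.22), ACAT2 (-0.66 ± 0.13) and the fatty acid desaturase SCD (-0.61 ± 0.16). Of 46 genes of G2 and mitosis 2 fell, the anaphase activator CDC20 by 0.52 ± 0.15 and survivin BIRC5 by 0.49 ± 0.13, and 0 did adjusted over the list alone (camera adjusted p = 0.00132, and adjusted p = 0.739 with an estimated correlation). Of the genes named here NOP16 alone kept its call whichever pair was left out. Without the 72 h pair FEN1 stood at -0.31, TK1 at -0.19, MCM7 at -0.17 and CDC45 at -0.13, none past the threshold (adjusted p = 0.467 to 0.822). The other calls ended there too, with MVD at -0.22, ACAT2 at -0.42, SCD at -0.27, CDC20 at -0.25, BIRC5 at -0.32, RRP9 at -0.47, MRTO4 at -0.56 and POLR3G at 0.63 (adjusted p = 0.0607 to 0.691). Without the 6 h pair MVD stood at -1.35, SCD at -0.95, TK1 at -0.94, MCM7 at -0.88, CDC45 at -0.87 and CDC20 at -0.78. Without the THP-1 24 h pair the calls of SCD, TK1, MCM7, CDC45, CDC20 and BIRC5 ended (adjusted p = 0.0551 to 0.0860), and without the THP-1 72 h pair those of MCM7, CDC45 and CDC20 (0.0614 to 0.0772).

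Of 47 ATF4 targets of amino acid metabolism 3 fell and 3 rose, both over all genes and adjusted over the list alone (camera adjusted p = 0.00677 for lower, and adjusted p = 0.739 with an estimated correlation). The amino acid carriers SLC7A5 and SLC1A5 fell by 0.71 ± 0.14 and 0.50 ± 0.15, while SLC38A2, another carrier, rose by 0.57 ± 0.12. Of 29 heat shock and unfolded protein response genes 6 fell, among them SDF2L1 (-0.83 ± 0.13), HSPB1 (-0.72 ± 0.15) and CRELD2 (-0.52 ± 0.13), and adjusted over the list alone 8 fell and 3 rose (camera adjusted p = 0.0212, and adjusted p = 0.739 with an estimated correlation). Of 15 neutrophil and eosinophil granule genes 3 fell, PRG2 by 1.04 ± 0.30, CTSG by 0.55 ± 0.16 and RNASE2 by 0.54 ± 0.17, and 4 did adjusted over the list alone (camera adjusted p = 0.0212, and adjusted p = 0.739 with an estimated correlation). Without the 72 h pair SLC7A5 stood at -0.46, SLC1A5 at -0.28, SLC38A2 at 0.45, HSPB1 at -0.38 and CRELD2 at -0.44, none past the threshold (adjusted p = 0.203 to 0.530). PRG2, CTSG and RNASE2 stood at -0.58, -0.23 and -0.14 without it (0.460 to 0.832) and at -1.73, -0.87 and -0.97 without the 6 h pair. Their calls also ended without either THP-1 pair (0.0550 to 0.0991).

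Of 53 monocyte and macrophage maturation genes 15 rose and 3 fell in KASUMI-1, with the same counts adjusted over the list alone. The list's median was 0.09 and its mean 0.54 (camera adjusted p = 0.0388, and adjusted p = 0.739 with an estimated correlation). Of 25 stem and progenitor genes 5 rose and none fell, among them the transcription factors SOX4 (0.72 ± 0.13), ERG (0.63 ± 0.12) and RUNX1 (0.48 ± 0.13) and the Polycomb protein BMI1 (0.48 ± 0.14), and adjusted over the list alone 6 rose (camera adjusted p = 0.00989, and adjusted p = 0.739 with an estimated correlation). Gene-level counts do not separate RUNX1 from the RUNX1::RUNX1T1 fusion transcript of KASUMI-1. This RUNX1 value, and its difference from THP-1 given below, can hold both. Of 47 type I interferon response genes 8 rose and 2 fell, and adjusted over the list alone 14 rose and 5 fell (camera adjusted p = 0.0212, and adjusted p = 0.739 with an estimated correlation). TRIM22 rose by 1.86 ± 0.54, the transcription factor IRF1 by 1.05 ± 0.18 and PARP14 by 0.78 ± 0.14, and OASL fell by 0.78 ± 0.23. Of 24 antigen presentation genes HLA-DMB (1.45 ± 0.42) and cathepsin S, CTSS (1.07 ± 0.13) rose, also adjusted over the list alone (camera adjusted p = 0.0212, and adjusted p = 0.739 with an estimated correlation). Without the 72 h pair SOX4 stood at 0.60, ERG at 0.51, RUNX1 at 0.39, BMI1 at 0.24 and HLA-DMB at 0.995, none past the threshold (adjusted p = 0.0561 to 0.606). The interferon response genes lost their calls there too, with TRIM22 at 0.78, IRF1 at 0.56, PARP14 at 0.61 and OASL at -0.39 (0.0726 to 0.568). Without the 6 h pair TRIM22 stood at 3.30, OASL at -1.28 and BMI1 at 0.72. The calls of BMI1 and OASL also ended without either THP-1 pair (0.0617 to 0.0688), and that of RUNX1 without the 24 h one (0.0525). These were 11 called lists of 23 tested. Only the ribosome biogenesis, ATF4 and monocyte lists kept their call with RLE normalization and with each pair left out in turn.

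The second comparison asked the same of the resistant line. In THP-1 CD86 rose by 5.55 ± 0.25 on the log2 scale (adjusted p = 8.07e-11, edgeR's quasi-likelihood test), LY96 by 6.07 ± 0.34, the calcium-binding alarmin S100A12 by 5.71 ± 0.60 and LYZ by 3.42 ± 0.36. ITGAM rose by 2.74 ± 0.16, CD14, the lipopolysaccharide co-receptor of monocytes, by 2.40 ± 0.30 and CSF1R by 1.14 ± 0.14. The lipid antigen-presenting molecule CD1A rose by 6.42 ± 0.37, the amino acid carrier SLC7A8 by 5.64 ± 0.34 and GIMAP4 by 7.33 ± 0.31. FCRLA went from 3 to 1328 reads, a ratio of 495 (counting interval 169 to 2405), and TDRD9, a Tudor domain helicase, from 1 to 49 reads, a ratio of 54.8 (9.39 to 2209).

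Among genes with an average log2 CPM of at least 1, falls in THP-1 were led by the receptor tyrosine kinase ROS1 (-3.71 ± 0.37), the mucin MUC19 (-2.33 ± 0.29), the procollagen enhancer PCOLCE2 (-2.20 ± 0.30), IGSF10 (-2.15 ± 0.47), the adhesion protein CEACAM6 (-2.12 ± 0.26), the stem cell factor receptor KIT (-2.11 ± 0.26) and complement protease C1S (-2.10 ± 0.31). ACTL8 went from 15 to 2 reads, a ratio of 0.149 (0.0166 to 0.642). By edgeR's quasi-likelihood test 1046 genes rose and 457 fell, 510 and 148 of them at least 2-fold. The count was 386 without the 72 h pair, 628 without the 24 h pair, 454 without the pair block and 990 with DESeq2. Of 86 called genes chosen for naming, the calls of 29 ended without the 72 h pair and of 23 without the 24 h pair. KIT stood at -1.35 without the 72 h pair, C1S lost its call there (-1.40, adjusted p = 0.155), and IGSF10 and ACTL8 lost theirs without either pair (0.209 and 0.774 without 24 h, 0.0645 and 0.126 without 72 h).

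Among the lists, 29 of 53 monocyte and macrophage maturation genes rose and 1 fell in THP-1, and adjusted over the list alone 31 rose and 1 fell (limma camera adjusted p = 6.14e-23, and adjusted p = 0.145 with an estimated correlation). The scavenger receptor CD163 went from 3 to 142 reads, a ratio of 53.0 (17.8 to 260). Of 24 antigen presentation genes 8 rose, among them the class II genes HLA-DMB (3.46 ± 0.37), HLA-DMA (1.53 ± 0.22) and HLA-DRA (1.38 ± 0.26) and the lipid-presenting CD1D (1.10 ± 0.13), and adjusted over the list alone 9 did (camera adjusted p = 3.49e-07, and adjusted p = 0.581 with an estimated correlation). Of 31 cytokine and NF-kB target genes 11 rose, and adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 3.18e-05, and adjusted p = 0.512 with an estimated correlation). The chemokine CCL2 rose by 3.73 ± 0.25, the adhesion molecule ICAM1 by 2.25 ± 0.27, TNF by 2.16 ± 0.24 and the interleukin 1 antagonist IL1RN by 2.13 ± 0.16. Of 55 lysosome and autophagy genes 12 rose, and 15 did adjusted over the list alone (camera adjusted p = 3.18e-05, and adjusted p = 0.512 with an estimated correlation). They included the transcription factor MITF (1.96 ± 0.23) and the cathepsins CTSH (1.43 ± 0.15), CTSB (1.39 ± 0.14) and CTSZ (1.32 ± 0.13). Of 47 type I interferon response genes 10 rose, with HERC5 (2.55 ± 0.16), TRIM22 (2.54 ± 0.29), OAS1 (1.75 ± 0.22) and IFIT5 (1.49 ± 0.24), and 12 did adjusted over the list alone (camera adjusted p = 1.25e-04, and adjusted p = 0.512 with an estimated correlation). Without the 72 h pair the calls of IFIT5 (1.28, adjusted p = 0.113), HLA-DMA (1.22, 0.0516) and HLA-DRA (0.69, 0.379) ended, and HLA-DRA stood at 2.08 without the 24 h pair. The fitted value of CD163 was 8.85 without the 24 h pair, against 5.61 over both.

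Of 31 ERK feedback and immediate-early genes 9 rose, among them the ERK pathway inhibitors SPRY4 (2.30 ± 0.27) and SPRED1 (2.21 ± 0.24) and the transcription factors ETV1 (2.25 ± 0.21) and ETV5 (1.51 ± 0.15), and adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 0.00783, and adjusted p = 0.899 with an estimated correlation). Of 47 ATF4 targets 11 rose and 3 fell, and adjusted over the list alone 14 rose and 3 fell (camera adjusted p = 0.00753, and adjusted p = 0.512 with an estimated correlation). The secreted glycoprotein STC2 rose by 2.20 ± 0.28 and the angiogenic factor VEGFA by 1.45 ± 0.15, while the cystine carrier SLC7A11 fell by 1.72 ± 0.18 and the lipoprotein receptor VLDLR by 1.27 ± 0.17. Of 72 ribosomal protein and translation factor genes RPS29 alone rose, by 0.85 ± 0.13, also adjusted over the list alone, with a list median of 0.15 (camera adjusted p = 2.89e-04, and adjusted p = 0.918 with an estimated correlation). Reads of such genes that also map to their many processed pseudogenes were left out, so these genes may be undercounted. Of 15 granule genes 3 fell, DEFA4 (-2.73 ± 0.71), CTSG (-1.28 ± 0.17) and PRTN3 (-0.70 ± 0.18), and CAMP rose by 1.40 ± 0.32, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0238 for lower, and adjusted p = 0.891 with an estimated correlation). DEFA4 and PRTN3 lost their calls without either THP-1 pair (adjusted p = 0.107 and 0.124 without 24 h, 0.367 and 0.668 without 72 h). CAMP stood at 0.75 without the 72 h pair (0.675) and at 2.16 without the 24 h pair, and RPS29 at 0.64 without the 24 h pair (0.0794).

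Of 16 lymphoid and mast cell markers, genes of cell types other than these lines, 4 rose and 1 fell in THP-1, also adjusted over the list alone (camera adjusted p = 0.0429, and adjusted p = 0.581 with an estimated correlation). The T cell surface protein CD2 went from 0 to 21 reads, at least 7.83-fold higher, CD5 rose by 2.26 ± 0.51 and the B cell adaptor BLNK by 2.03 ± 0.29, and the B cell transcription factor PAX5 fell by 1.36 ± 0.37. The calls of CD2 and CD5 ended without either THP-1 pair (adjusted p = 0.211 and 0.429 without 24 h, 0.0592 and 0.115 without 72 h), and PAX5 stood at -0.84 without 72 h (0.626) and at -2.34 without 24 h. In all 10 lists were called in THP-1. Only the monocyte, antigen presentation, cytokine, lysosome and interferon lists kept their call with RLE normalization and with each pair left out in turn. Of the lists called lower in KASUMI-1, these were not called here: ribosome biogenesis had 1 member higher of 52 (camera adjusted p = 0.467), S phase 0 of 40 by edgeR's test, with 2 at an unadjusted p under 0.05 (0.273), SREBP targets 1 higher of 39 (0.381), heat shock and unfolded protein response 1 higher of 29 (0.375) and G2 and mitosis 1 higher of 46 (0.972, with a median of -0.00 and a mean of 0.02). For the heat shock list the difference between the lines was itself not called (camera adjusted p = 0.257).

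**Figure D1:**
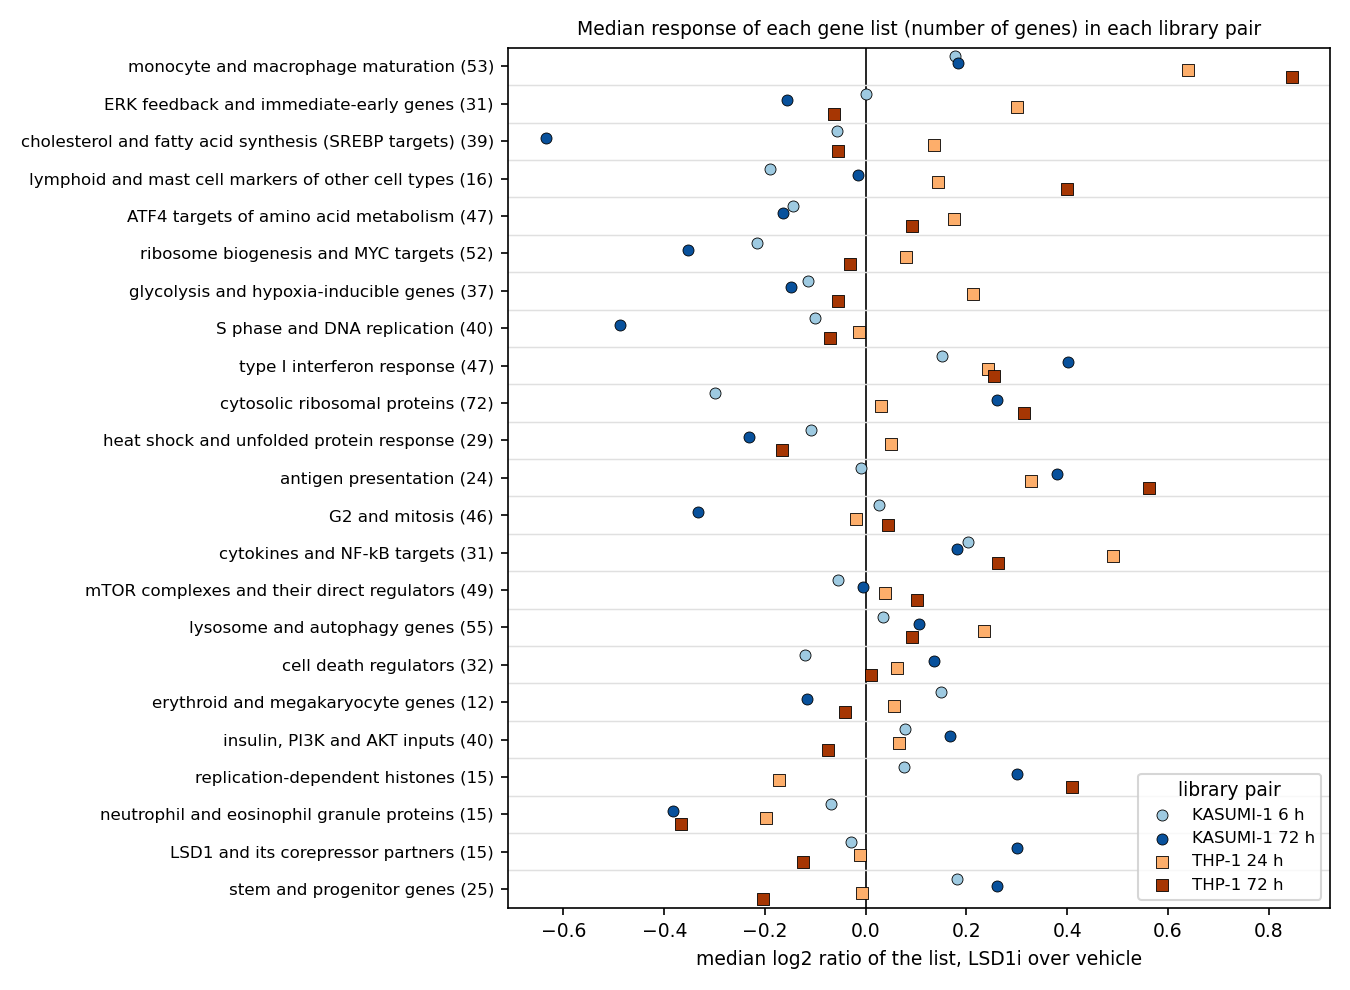
Median log2 ratio of LSD1i over vehicle (x axis) for each of 23 gene lists (y axis, number of genes in brackets) in each library pair, ordered by the median difference between the lines. The monocyte and macrophage list lies at 0.18 in both KASUMI-1 pairs and at 0.64 and 0.85 in the THP-1 pairs at 24 and 72 h, and the SREBP list reaches -0.64 only in the KASUMI-1 72 h pair among the 4.

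The third comparison tested the difference of response between the lines, KASUMI-1 minus THP-1, whose early pairs differ in time (6 and 24 h). By edgeR's quasi-likelihood test the difference was positive for 421 genes and negative for 493. A positive difference can come from a rise in KASUMI-1, a fall in THP-1 or both, and a negative one from the reverse. The share of positive differences, 46.1%, was 34.3% with DESeq2 and 70.9% with scaling by library size alone, an alternative added after the calls were seen. CAMSAP2 stood 4.60 ± 0.38 apart, with 4.37 in KASUMI-1 and -0.23 in THP-1. Other genes with a positive difference were the membrane protein IGSF3 (2.92 ± 0.37), the phosphatase regulator PPP1R16B (3.12 ± 0.43), the Ras activator RASGRP3 (2.79 ± 0.50), PRUNE2 (2.76 ± 0.51) and SOCS2, a suppressor of cytokine signalling (2.62 ± 0.32). Most of the SOCS2 difference was a fall in THP-1 (-2.09, with 0.52 in KASUMI-1). PRKCE, a protein kinase C, went from 1 to 18 reads in KASUMI-1, a ratio of 13.6 (2.14 to 565). In THP-1 the response was higher for the alarmins S100A8 (-4.34 ± 0.86) and S100A9 (-4.19 ± 0.67), the mitochondrial calcium uniporter subunit MCUB (-4.16 ± 0.30), the matrix proteoglycan VCAN (-4.04 ± 0.997) and CD1A, which had 0 to 3 reads per library in KASUMI-1. FJX1 had 0 vehicle and 10 LSD1i reads in THP-1, at least 3.73-fold higher. KIT differed by 1.91 ± 0.33 and ITGAM by -1.38 ± 0.36 (adjusted p = 0.00262 and 0.0318, edgeR's quasi-likelihood test), CD86 by -1.39 ± 0.40 (adjusted p = 0.0501), and LYZ by -0.60 ± 0.47 (adjusted p = 0.499), neither past the threshold. The count was 1705 without the KASUMI-1 6 h pair, 178 without the THP-1 24 h pair, 166 without the THP-1 72 h pair and 22 without the pair block. Of 72 called genes chosen for naming, the calls of 44 ended without the THP-1 72 h pair, of 43 without THP-1 24 h, of 20 without KASUMI-1 72 h and of 6 without KASUMI-1 6 h. Without THP-1 72 h S100A8 stood at -2.71 and S100A9 at -2.62, and the calls of RASGRP3 (2.11, adjusted p = 0.0663) and KIT (1.14, 0.0925) ended. The call of PRKCE ended without KASUMI-1 72 h (2.34 from a fitted 3.56, adjusted p = 0.354), THP-1 24 h (0.152) or THP-1 72 h (0.129), and its fitted value was 6.83 without KASUMI-1 6 h. The call of CD1A ended without KASUMI-1 72 h (1.0) or THP-1 72 h (0.0618), and that of FJX1 without THP-1 24 h (0.0984) or 72 h (0.287). PRUNE2 stood at 4.59 without KASUMI-1 72 h and lost its call without THP-1 24 h (0.0599). ITGAM lost its call without KASUMI-1 6 h (-0.78, 0.500) or either THP-1 pair (0.183 at 24 h and 0.114 at 72 h).

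By limma camera 13 lists differed in response. Of these, only the monocyte, ATF4 and ribosome biogenesis lists kept their call with RLE normalization and with each pair left out in turn. A lower response in KASUMI-1 was called for ribosome biogenesis (adjusted p = 1.22e-07, 4 of 52 genes lower, 12 adjusted over the list alone), SREBP targets (4.59e-06, 3 of 39, 9 over the list alone) and S phase (0.00106, 1 of 40, 0 over the list alone), each with adjusted p = 0.726 with an estimated correlation. So it was for ribosomal proteins (4.57e-04, 1 of 72, 1 over the list alone), glycolysis and hypoxia-inducible genes (0.00348, 6 of 37 lower and 2 higher, 11 and 2 over the list alone) and G2 and mitosis (0.0110, 2 of 46, 2 over the list alone), each with adjusted p = 0.726 with an estimated correlation. The same held for ERK feedback genes (0.0117, 5 of 31 lower and 2 higher, 8 and 2 over the list alone), lysosome genes (0.0226, 7 of 55, 7 lower and 1 higher over the list alone), antigen presentation (0.0398, 2 of 24, 4 over the list alone) and cytokines (0.0434, 5 of 31, 5 over the list alone), again with adjusted p = 0.726 with an estimated correlation. The monocyte list was lower in KASUMI-1 (4.59e-06, 12 of 53 lower and 1 higher, 18 and 3 over the list alone), as were ATF4 targets (1.65e-05, 10 of 47 lower and 2 higher, 15 and 3 over the list alone), both with adjusted p = 0.344 with an estimated correlation. Stem and progenitor genes were higher in KASUMI-1 (0.0273, 4 of 25 higher and 1 lower, 6 and 2 over the list alone, and adjusted p = 0.726 with an estimated correlation). Without the KASUMI-1 6 h pair the ribosomal protein list turned to the other direction (adjusted p = 0.766), as the G2 and mitosis list did without the KASUMI-1 72 h pair (0.945).

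The mTOR axis gave the study its times. Members of the mTOR list moved in both directions, and camera, which tests for a shared direction, called the list in neither line. In KASUMI-1, 5 of 49 mTOR complex and regulator genes rose and 5 fell, 5 and 6 adjusted over the list alone, with a median of -0.01 and a mean of 0.02 (camera adjusted p = 0.575). In THP-1, 3 rose and 2 fell, 4 and 2 adjusted over the list alone (camera adjusted p = 0.358), and the difference of response was not called (camera adjusted p = 0.260). DDIT4 (REDD1), a stress-induced inhibitor of mTOR complex 1, rose by 1.08 ± 0.22 in KASUMI-1 and by 1.18 ± 0.22 in THP-1. Its KASUMI-1 value was 0.42 without the 72 h pair (adjusted p = 0.335) and 1.78 without the 6 h pair, and the THP-1 call was lost without the 24 h pair (1.02, adjusted p = 0.115, edgeR's quasi-likelihood test). In KASUMI-1 the sestrin SESN1 (0.78 ± 0.16) and the methionine sensor SAMTOR (0.67 ± 0.16), both negative regulators, rose, and MLST8, a subunit of both mTOR complexes, fell by 0.66 ± 0.13. Without the 72 h pair these stood at 0.40, 0.37 and -0.51, none past the threshold (adjusted p = 0.375, 0.452 and 0.17). SESN1 stood at 1.17 without the 6 h pair. In THP-1 the DDIT4 relative DDIT4L rose by 1.75 ± 0.40, and the Rag GTPase RRAGD and the sestrin SESN3 fell by 0.51 ± 0.13 and 0.48 ± 0.13. These 3 calls ended without either THP-1 pair (adjusted p = 0.0842 to 0.448). SESN3 was at 0.43 ± 0.13 in KASUMI-1 (adjusted p = 0.0469) and differed between the lines (0.91 ± 0.19, adjusted p = 0.00887, edgeR's quasi-likelihood test), a call that ended without THP-1 24 h (0.135) or 72 h (0.0600). MTOR was at -0.01 ± 0.12 and -0.11 ± 0.12, DEPTOR at 0.12 ± 0.16 and 0.06 ± 0.17 and SESN2 at 0.06 ± 0.17 and 0.54 ± 0.17 in KASUMI-1 and THP-1, none past the threshold. No name in the table matched RPTOR, which was not analysed here.

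Upstream, IRS1, the insulin receptor adaptor, rose by 2.23 ± 0.29 in THP-1 (adjusted p = 3.89e-05, edgeR's quasi-likelihood test), from 37 to 130 reads at 24 h and from 34 to 169 at 72 h. Its relative IRS2 fell by 0.79 ± 0.18 and the growth factor receptor IGF1R by 1.09 ± 0.20, and the PI3K regulatory subunit PIK3R6 rose by 1.77 ± 0.41. IRS1 had 2 to 8 reads per library in KASUMI-1, where no change was detectable at this depth (0.35 ± 0.75), and the difference between the lines was not past the threshold (adjusted p = 0.224). In KASUMI-1 PIK3IP1, an inhibitor of PI3K, rose by 1.24 ± 0.19, the subunit PIK3R3 by 0.80 ± 0.18 and the adaptor GAB2 by 0.64 ± 0.13. PIK3IP1 and GAB2 also rose in THP-1, by 1.07 ± 0.27 and 1.31 ± 0.13. Without the KASUMI-1 72 h pair PIK3IP1 stood at 0.74 (adjusted p = 0.0565) and PIK3R3 at 0.32 (0.510), and PIK3R3 at 1.29 without the 6 h pair. In THP-1 the calls of IRS1 (0.0514), IRS2 (-0.44, 0.637), IGF1R (0.116) and PIK3R6 (0.106) ended without the 72 h pair. Without the 24 h pair IRS2 stood at -1.19 and the call of PIK3R6 ended (0.331). Over the list of 40 insulin, PI3K and AKT inputs 7 rose and 3 fell in KASUMI-1, 7 and 4 adjusted over the list alone (camera adjusted p = 0.223). In this list 6 rose and 3 fell in THP-1, 6 and 4 adjusted over the list alone, with a median of -0.02 and a mean of 0.11 (camera adjusted p = 0.884). The difference of response was not called either (camera adjusted p = 0.552).

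KDM1A, the inhibitor's target, was at -0.17 ± 0.13 in KASUMI-1 and at -0.07 ± 0.13 in THP-1, neither past the threshold. GFI1, which recruits LSD1 to its target genes, rose by 0.63 ± 0.13 and 0.52 ± 0.13. Its relative GFI1B rose in KASUMI-1 by 1.73 ± 0.38 from 15 to 22 vehicle reads per library, was at -0.80 ± 0.49 in THP-1, and differed between the lines (2.53 ± 0.62, adjusted p = 0.0242, edgeR's quasi-likelihood test). CD34, a stem cell surface protein, was at 0.41 ± 0.15 and 0.12 ± 0.28, and KIT at -0.20 ± 0.20 in KASUMI-1, none past the threshold. The KASUMI-1 calls of GFI1 and GFI1B ended without the 72 h pair (0.53 and 1.07, adjusted p = 0.124 and 0.304), and that of GFI1 in THP-1 without either pair (0.451 and 0.167). The difference of GFI1B ended without KASUMI-1 72 h (0.0841), THP-1 24 h (0.287) or THP-1 72 h (0.0776). MYC was at -0.35 ± 0.13 in THP-1 (adjusted p = 0.116).

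**Figure D2:**
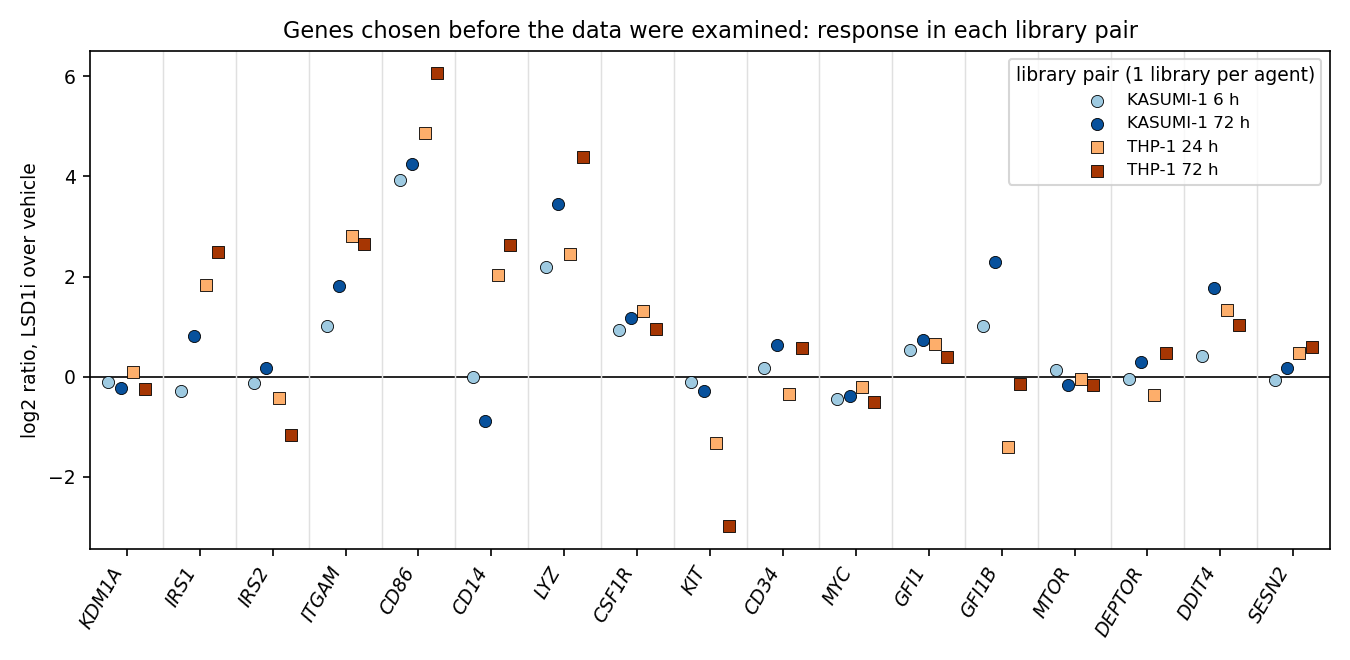
Log2 ratio of LSD1i over vehicle (y axis) for 17 genes chosen before the data were examined (x axis), with 1 point for each of the 4 library pairs and no error bars, since each point rests on 1 library per agent. CD86 lies between 3.92 and 6.05 in the 4 pairs, KDM1A between -0.24 and 0.09, and KIT at -1.32 and -2.99 in THP-1.

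Taken per pair, which is a description of 1 library against another with no replicate check, more genes stood apart at 72 h than at the earlier time in both lines. At a mean of at least 2 CPM (counts scaled to a common library size), 89 genes stood at least 2-fold apart in KASUMI-1 at 6 h with a counting interval that excluded equality, 86 of them higher, and 487 at 72 h, 373 higher. In THP-1 the numbers were 359 at 24 h, 312 higher, and 523 at 72 h, 370 higher. GIMAP4, CD86, KCTD12, IGSF3 and the membrane protein MS4A4A led the 6 h pair, with ratios of 6.28, 3.92, 3.71, 3.69 and 3.23 on the log2 scale. PI16 (6.76) and FCRLA (6.70) followed GIMAP4 (6.99) among the highest of the KASUMI-1 72 h pair, where the glycolytic regulator PFKFB4 (-1.56) was among the lowest. PI16, FCRLA and GIMAP4 had 1, 3 and 3 reads in the KASUMI-1 vehicle libraries together, so their ratios and order depend on the prior count. The guidance molecule RGMB stood at 5.20 in THP-1 at 24 h and CD1C at 6.53 at 72 h, while the inhibitor of metalloproteinases TIMP3 (-2.91) and TEAD3 (-2.96) were among the lowest at 72 h and thrombospondin THBS4 (-1.70) and SOCS2 (-1.66) at 24 h. The lowest at 6 h were RTN4R (-1.43), sphingosine kinase SPHK1 (-1.18), RPL15P3 (-1.03), GPRC5C (-0.99) and the kinase SIK1 (-0.98). CLEC4GP1 (-1.92) joined IGLL1 (-3.15), MT2A (-2.21) and HES6 (-1.58) at the bottom of the KASUMI-1 72 h pair.

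Pairs were compared over the genes with a mean of at least 2 CPM in both. Among 10810 such genes, 79 were at least 2-fold higher in KASUMI-1 at 6 h, and 74 of these were so at 72 h, against 2.36 for independent lists. Among 11133 genes, 230 were 2-fold higher in both THP-1 pairs, against 9.09. At 72 h, among 10217 genes, 85 were 2-fold higher in both lines (7.03 for independent lists) and 3 were lower in both (0.559). Across genes, which are not independent replicates, the log2 ratios of the pairs correlated at r = 0.703 (Spearman 0.644) within KASUMI-1 and at 0.791 (0.533) within THP-1. No library is shared by any 2 pairs. Between lines r was 0.395 (0.277) for the 72 h pairs, 0.280 (0.0691) for KASUMI-1 6 h with THP-1 72 h, 0.263 (0.0359) for KASUMI-1 72 h with THP-1 24 h and 0.213 (-0.0295) for KASUMI-1 6 h with THP-1 24 h.

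List medians also differed between the pairs, with 1 pair per time in each line. The S phase list stood at -0.10 at 6 h, the 26.1 percentile of 10000 random lists matched on expression, and at -0.49 at 72 h, the 0 percentile, in KASUMI-1. SREBP targets went from -0.06 to -0.64 and G2 and mitosis genes from 0.03 to -0.33, while ribosome biogenesis was low at both times (-0.22 and -0.35, both at the 0 percentile). The ribosomal protein list took opposite signs at the KASUMI-1 times, -0.30 at 6 h (0 percentile) and 0.26 at 72 h (100 percentile), and stood at 0.03 and 0.31 in THP-1 at 24 and 72 h. The KASUMI-1 72 h vehicle library was the shallowest of the 8.

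A further comparison took all 4 pairs together. By edgeR's quasi-likelihood test 611 genes rose and 126 fell with the inhibitor over both lines. Of the genes called within each line, 296 rose in both, against 73.5 for independent lists of those sizes, and 38 fell in both, against 23.3. Those called in opposite directions numbered 18 (higher in KASUMI-1 and lower in THP-1, against 32.1) and 14 (the reverse, against 53.2). CSF1R, CD86, LYZ and cathepsin S were among those higher in both lines. The count over 4 pairs was 382 without the THP-1 24 h pair, 226 without the THP-1 72 h pair, 488 without the pair block and 1382 with no filter on low counts.

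The last comparison set the lines against each other without inhibitor, with the 2 vehicle libraries of a line as its replicates. Of 15456 genes 4080 were higher in KASUMI-1 and 4656 higher in THP-1 by edgeR's quasi-likelihood test, 2580 and 3283 of them at least 2-fold. KDM1A was higher in KASUMI-1 by 1.08 ± 0.18 (adjusted p = 5.20e-04), as were CD34 (9.18 ± 0.24), KIT (5.74 ± 0.32), DEPTOR (3.28 ± 0.18), MYC (1.82 ± 0.19), DDIT4 (1.02 ± 0.33), SESN2 (0.92 ± 0.22) and MTOR (0.41 ± 0.16). Lower in KASUMI-1 were LYZ (-4.39 ± 0.28), ITGAM (-4.16 ± 0.34), IRS1 (-2.97 ± 0.50), IRS2 (-2.87 ± 0.23) and CSF1R (-2.83 ± 0.25). CD14 had 2 reads in the KASUMI-1 vehicle libraries together and 37 and 24 in those of THP-1. GFI1 (-0.12 ± 0.18), GFI1B (0.42 ± 0.39) and CD86 (0.10 ± 0.37) were not past the threshold.

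Along chromosome 1, 33 consecutive expressed genes from PABPC4 to SLC2A1 (positions 39799075 to 43197126 of NCBI36, 1-based, as the deposited table gives them) were all higher in THP-1 by at least 2-fold, a stretch singled out after its values were seen. The next longest run of genes higher in THP-1 along any autosome held 9. The median difference was -2.67 on the log2 scale, from -8.40 for the exonuclease EXO5 to -1.42 for PABPC4, with -7.76 for the MYC relative MYCL, -7.41 for BMP8B, -5.16 for the actin regulator CAP1, -4.05 for PPT1 and -1.96 for YBX1. Over the 5 Mb on either side the median was 0.18 for 44 genes below the stretch and -0.44 for 48 genes above it. Past SLC2A1 the gap went on in part. A further run of 6 genes, MED8 to ST3GAL3, was at least 2-fold higher in THP-1. Between the runs lay EBNA1BP2 (0.03), CDC20 (-2.48) and ELOVL1 (-0.39). The stretch took 0.343% of the KASUMI-1 and 3.75% of the THP-1 vehicle counts.

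**Figure D3:**
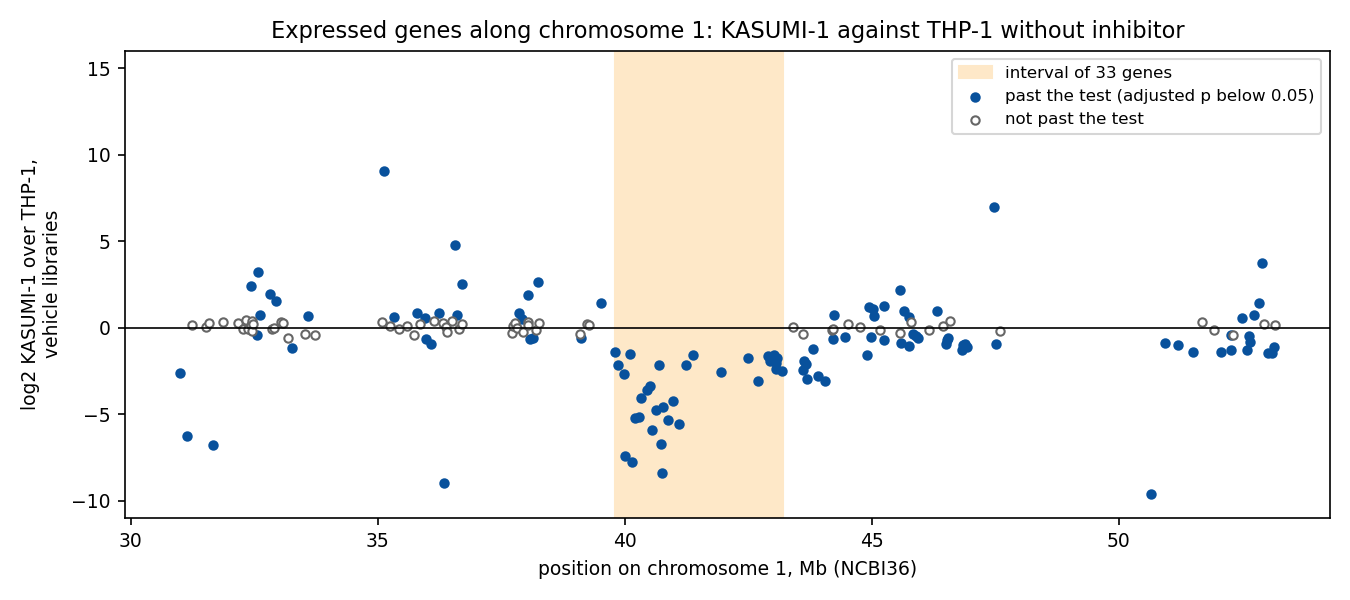
Log2 difference between KASUMI-1 and THP-1 vehicle libraries (y axis) for expressed genes along chromosome 1 (x axis, Mb, NCBI36), with filled points for genes past edgeR's test and the stretch of 33 genes shaded. The shaded genes lie between -8.40 and -1.42.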

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

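The tests of the 6 h pair, of the 72 h pairs across lines and of the chromosome 1 stretch were chosen after the result was seen, while the tests of depth, of the expression trend and of low counts were planned. Each gene and list here drew attention because its response to the inhibitor differed between KASUMI-1 and THP-1 by edgeR's quasi-likelihood test or limma camera, and each value is KASUMI-1 minus THP-1 on the log2 scale. A positive value can come from a rise in KASUMI-1, a fall in THP-1 or both. In THP-1 KIT, MUC19, IGSF10, SLC7A11, IGF1R and BCL2 stood at -2.11, -2.33, -2.15, -1.72, -1.09 and -0.66. Their KASUMI-1 values were -0.20, 0.06, -0.05, 0.17, 0.20 and 0.04. CAMSAP2 instead rose by 4.37 in KASUMI-1, with -0.23 in THP-1. Surface, secreted and transporter genes with a positive value were KIT (1.91), MUC19 (2.39), PCOLCE2 (1.68), IGSF10 (2.10), C1S (1.77), IGSF3 (2.92), KCTD12 (2.17), MS4A4A (1.54), THBS4 (2.29), IGF1R (1.30), SLC38A2 (0.69) and SLC7A11 (1.88). Other genes in the same direction were GFI1B (2.53), CAMSAP2 (4.60), PPP1R16B (3.12), RASGRP3 (2.79), PRUNE2 (2.76), SOCS2 (2.62), RCOR3 (0.71), ERG (1.38), RUNX1 (0.81), CDK6 (1.16), SESN3 (0.91), ETV1 (1.58) and BCL2 (0.70). Of these, CAMSAP2, IGSF3, KCTD12, MS4A4A, PPP1R16B, SLC7A11 and SOCS2 kept their call whichever of the 4 pairs was left out. The others lost it without at least 1 pair: without THP-1 72 h KIT (1.14), C1S (1.06), PCOLCE2, IGSF10, MUC19, THBS4, IGF1R, SLC38A2, GFI1B, RASGRP3, RCOR3, ERG, RUNX1, SESN3, ETV1 and BCL2 (adjusted p = 0.0600 to 0.408). Without THP-1 24 h MUC19, IGSF10, THBS4, SLC38A2, GFI1B, PRUNE2, RCOR3, ERG, RUNX1, CDK6, SESN3, ETV1 and BCL2 did (0.0578 to 0.295), and without KASUMI-1 72 h THBS4, SLC38A2, GFI1B, RCOR3, ETV1 (1.02) and BCL2 (0.0551 to 0.372). MUC19 stood at 1.46 without KASUMI-1 6 h, PCOLCE2 at 2.53 without THP-1 24 h and PRUNE2 at 4.59 without KASUMI-1 72 h.

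The value was negative for the blood cell and immune genes ITGAM (-1.38), S100A8 (-4.34), S100A9 (-4.19), VCAN (-4.04), NFE2 (-1.01), CD79B (-1.27), OASL (-1.76), HERC5 (-1.82), HLA-DMA (-1.27), ICAM1 (-1.67) and TNF (-2.04). It was also negative for the lysosomal and metabolic genes MITF (-2.22), CTSH (-1.49), CTSB (-1.14), CTSZ (-1.53), HK1 (-0.65), HK2 (-1.59), PFKFB4 (-1.14), MCUB (-4.16), STC2 (-2.46), VEGFA (-1.52), SLC7A5 (-0.97) and ACAT2 (-0.75), and for the signalling genes SPRY4 (-2.86), SPRED1 (-1.55), ETV5 (-1.40), SPHK1 (-1.18), GAB2 (-0.66), MLST8 (-0.73), RGMB (-3.35) and TRIB2 (-1.76). RPS29 (-1.59), NOP16 (-0.80), MRTO4 (-0.75), BIRC5 (-0.74), CDC25B (-0.86), TNFRSF10A (-1.001), BID (-0.86) and SDF2L1 (-0.73) showed the same direction. A negative value can come from a rise in THP-1, as for S100A8 (4.03), from a fall in KASUMI-1, or both. In KASUMI-1 NOP16, MRTO4, MLST8, ACAT2 and SDF2L1 stood at -0.68, -0.65, -0.66, -0.66 and -0.83. Their THP-1 values were 0.12, 0.10, 0.07, 0.09 and -0.09. For genes with 0 to 3 reads in a group of a line the fitted value depends on the prior count and is no bound: BHLHE22 (5.60), PRKCE (3.56), PI16 (7.54), RAB11FIP5 (-5.22), FUT7 (-3.68), CD1A (-7.76), TDRD9 (-4.99) and FJX1 (-5.80). Of the 217 genes named, 72 differed in this way. In this direction and among the genes with few reads, CTSH, CTSZ, ETV5, HERC5, HK2, MCUB, RGMB, RPS29, S100A8, S100A9, STC2, VCAN and VEGFA kept their call whichever pair was left out, and each of the others lost it without at least 1. Without KASUMI-1 6 h ITGAM (-0.78), HLA-DMA (-0.80), MITF, NFE2, HK1 and BHLHE22 did (adjusted p = 0.0529 to 0.500). Without KASUMI-1 72 h ACAT2, BIRC5, GAB2, HK1, MLST8, MRTO4, PFKFB4 (-0.51), SDF2L1, TNFRSF10A, BHLHE22, CD1A, FUT7, PRKCE (2.34) and RAB11FIP5 (-3.17) did (0.0504 to 1.0). Without THP-1 24 h ACAT2, BID, BIRC5, CD79B, CDC25B, GAB2, HK1, HLA-DMA, ICAM1, ITGAM, MLST8, MRTO4, NFE2, NOP16, OASL, PFKFB4, SDF2L1, SLC7A5, SPHK1, SPRED1, SPRY4, TNF, TNFRSF10A, TRIB2, BHLHE22, FJX1, FUT7, PI16, PRKCE and RAB11FIP5 did (0.0590 to 0.390). Without THP-1 72 h ACAT2, BID, BIRC5, CDC25B, CTSB, GAB2, HK1, HLA-DMA, ITGAM, MITF, MLST8, MRTO4, NFE2, NOP16, OASL, PFKFB4, SDF2L1, SPHK1, SPRED1, TNFRSF10A, TRIB2, BHLHE22, CD1A, FJX1, FUT7, PRKCE, RAB11FIP5 and TDRD9 did (0.0524 to 0.287). PFKFB4 stood at -1.74, PRKCE at 6.83 and FUT7 at -6.74 without KASUMI-1 6 h, and S100A8 at -2.71 and S100A9 at -2.62 without THP-1 72 h.

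The lists that differed by camera had these adjusted p-values: monocyte and macrophage maturation 4.59e-06, stem and progenitor genes 0.0273, ATF4 targets 1.65e-05, SREBP targets 4.59e-06, glycolysis and hypoxia-inducible genes 0.00348, lysosome and autophagy 0.0226, ribosomal proteins 4.57e-04, ribosome biogenesis 1.22e-07, S phase 0.00106, G2 and mitosis 0.0110, antigen presentation 0.0398, cytokines 0.0434 and ERK feedback 0.0117. With an estimated correlation none of these 13 passed, with a lowest adjusted p of 0.344.

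The first pattern weighed was the fall of ribosome biogenesis, S phase and SREBP genes in KASUMI-1, where the 72 h vehicle library was the shallowest. Thinning all libraries to its total left the pooled median of the 131 members in the 72 h pair at -0.456 (bootstrap interval over members -0.541 to -0.404, against -0.45 unthinned). Random thinning hardly changes the ratio of well-read genes whatever its cause, so this could not decide on the depth or quality of that library. Taking out a trend on expression and exon length left the median over both pairs at -0.294 (-0.331 to -0.266), so that trend was not the whole cause. Ribosome biogenesis was low in the 6 h pair too, at -0.215 (-0.273 to -0.163), below the 2.5 percentile of random lists matched on expression (-0.156). Its low value was thus not confined to the 72 h pair. That interval runs over genes, and 1 library per agent gives no spread between libraries. The ribosomal protein list was also low at 6 h but not at 72 h, so a low list in 1 pair need not recur. For S phase (-0.10 at 6 h, -0.159 to -0.0393, within the range of the random lists) and SREBP targets (-0.0572, -0.129 to 0.0177), an effect of time and of the single 72 h pair cannot be told apart, since each time had 1 pair.

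The second pattern was the stronger rise of monocyte and macrophage genes in THP-1. Over the 29 members with a mean of at least 2 CPM in each line the median difference was -0.433 (-0.822 to -0.0578, against -0.531 over all members). That mean held the LSD1i libraries, so members low in vehicle could enter through their own rise. The value is thus only weak evidence against members too low to be seen in KASUMI-1 as the whole cause. At 72 h in both lines the median difference over all members was -0.852 (-1.31 to -0.165). Members with few reads in KASUMI-1, such as CD163 (0 vehicle and 5 LSD1i reads) and S100A12 (3 and 6), can lower that value at any time. Its interval runs over genes of 1 pair per line. It is thus only weak evidence against the longer early exposure of THP-1 as the whole cause for the list with its low members. Over the 29 members the median difference at 72 h was -0.428 (-0.978 to 0.101), so for these the line and the longer early exposure cannot be told apart. The difference between the lines themselves stays open, with 1 library per condition.

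The third pattern was the chromosome 1 stretch higher in THP-1 vehicle libraries, whose 33 genes were each chosen for a gap of at least 1 on the log2 scale. With the 10098 expressed genes in random order the longest run was 9 over 1000 orders, as was the next longest run along the chromosomes, against 33 here. This argues against reads of single genes shared with pseudogenes or paralogs as the whole cause. Loss of both copies in KASUMI-1 would leave no reads there, yet each gene had at least 11 in its vehicle libraries. Genes such as CAP1 (343 and 325 CPM in them) and YBX1 (1756 and 1943) argue against loss of the whole stretch. MYCL had only 0.13 and 0.27 CPM there, against 39.1 and 41.6 in THP-1. So few reads cannot exclude a loss of both copies in a part of the stretch. Loss of 1 of 2 copies was weighed with the same choice of genes: the other expressed genes, lowered by 1 and kept where they then reached -1, had a median of -1.65, against -2.67 in the stretch (-4.27 to -2.15). So such a loss was not the whole cause. The LSD1i libraries are of the same lines and times, so a difference between the lines recurs there and is no independent check. In them the median was -2.91, the lowest of 9329 other windows of as many genes -1.35 and the median of the 14 flanking genes -1.24, above that window. That flanking median pools unlike sides. In the vehicle libraries the flanking genes below the stretch lay between -0.62 (MYCBP) and 1.44 (MACF1). Above it the run of 6 genes from MED8 to ST3GAL3 was also at least 2-fold lower in KASUMI-1. The pooled median could thus not decide on the copies. More copies in THP-1 and regional activation, which was not tested, cannot be told apart from these values, and a part played by fewer copies in KASUMI-1 stays open.

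The 737 genes called over the 4 pairs were set against the other ways of swapping agents within pairs. There are 8 such assignments, too few for a share under 0.05. The real one, 1 of 8 with that many calls, gave 737 and the highest of the others 3.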

How the results depend on the processing

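Scaling by library size alone was chosen after seeing the data for the gene calls, and before for the pairs, as were the other alternatives. The calls depended on the matched pairs: without the pair block 100 genes were called in KASUMI-1, 454 in THP-1, 22 for the difference and 488 over the 4 pairs, because the spread then held the differences between times. Of the 737 genes over the 4 pairs 9 had the opposite sign there. Leaving out a pair in turn gave 306 (without KASUMI-1 72 h) to 2741 genes in KASUMI-1, with 1238 without THP-1 24 h. It gave 386 (without THP-1 72 h) to 2211 in THP-1, with 628 without THP-1 24 h. For the difference it gave 166 (without THP-1 72 h) to 1705 (without KASUMI-1 6 h), with 178 without THP-1 24 h, and over the 4 pairs 226 (without THP-1 72 h) to 836, with 382 without THP-1 24 h. Called lists numbered 5 (without KASUMI-1 72 h) to 12 in KASUMI-1, 6 (without THP-1 24 h) to 9 in THP-1, and 10 for the difference whichever pair was left out. Leaving out a vehicle library gave 7157 to 8864 genes between vehicle libraries, 3 of the 8736 with the opposite sign without the KASUMI-1 6 h library. Where a line kept 1 pair, that pair was assumed to vary like the others. A fit of 1 line's libraries alone gave 970 genes in KASUMI-1 and 2162 in THP-1. DESeq2 called 990 genes in THP-1, dropping the filter on low counts raised the count over the 4 pairs to 1382, and library size alone gave 1204 in KASUMI-1, the cause not tested. The 1945 and 1503 genes of the lines shared 1810 and 1494 calls with RLE normalization, and no called gene changed sign with RLE, DESeq2, limma-voom or library size alone. Scaling did move the share of higher calls: in KASUMI-1 58.0% against 49.8% with RLE, 44.9% with DESeq2 and 73.7% with library size alone. In THP-1 it was 69.6% against 59.1% with library size alone. For the difference it was 46.1% against 34.3% with DESeq2 and 70.9% with library size alone, and between vehicle libraries 46.7% against 34.7% with library size alone. That scaling shifted the median of all genes by -0.10 in THP-1, 0.14 for the difference and -0.23 between vehicle libraries. In the pairs it moved the share of higher 2-fold genes from 76.6% to 62.6% in KASUMI-1 and from 70.8% to 56.6% in THP-1 at 72 h, where the median of all genes shifted to -0.13. With an estimated correlation limma camera called 0 lists in each comparison (0, 1 and 2 of 23 at an unadjusted p under 0.05 in KASUMI-1, in THP-1 and for the difference), and fry 0, 1 (monocyte genes, adjusted p = 0.0400) and 0 (2, 6 and 3 unadjusted). The ribosomal protein list turned higher in KASUMI-1 without its 6 h pair (adjusted p = 0.00783), with a range of 8.71e-13 to 0.233 over the left-out pairs, and turned for the difference (0.766, from 1.37e-15). The G2 list turned for the difference without the KASUMI-1 72 h pair (0.945, from 3.89e-06). The cause was not tested. Of the called lists 3 of 11 in KASUMI-1, 5 of 10 in THP-1 and 3 of 13 for the difference kept their call with RLE and with every pair left out. Over the alternatives, the 96, 86 and 72 called genes named in KASUMI-1, in THP-1 and for the difference kept their call 753, 842 and 507 times, lost it 299, 102 and 213 times and reversed 0 times. A mean of at least 10 CPM left 39, 238, 168 and 251 2-fold genes in the KASUMI-1 6 and 72 h and THP-1 24 and 72 h pairs, since fewer genes enter. It also moved r to 0.109 (KASUMI-1 6 h with THP-1 24 h) and 0.123 (KASUMI-1 72 h with THP-1 24 h), and turned Spearman's rho of the latter from 0.0359 to -0.0268. Among the genes fixed beforehand, left-out pairs ended several calls by edgeR's test. ITGAM lost its call in KASUMI-1 without its 72 h pair (adjusted p = 0.127) and for the difference without KASUMI-1 6 h (0.500) or either THP-1 pair (0.183 at 24 h, 0.114 at 72 h). GFI1 lost it in KASUMI-1 without 72 h (0.124) and in THP-1 without 24 h (0.451) or 72 h (0.167). GFI1B lost it in KASUMI-1 without 72 h (0.304) and for the difference without KASUMI-1 72 h (0.0841), THP-1 24 h (0.287) or THP-1 72 h (0.0776). Without THP-1 72 h the calls of IRS1 (0.0514), IRS2 (0.637, from -0.79 to -0.44 on the log2 scale) and of KIT for the difference (0.0925, from 1.91 to 1.14) ended. KIT in THP-1 went from -2.11 to -1.35, while IRS2 was at -1.19 without THP-1 24 h. Depth limits low genes such as IRS1, with 2 to 8 reads per KASUMI-1 library.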

Other observations

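TNFRSF10B, the TRAIL receptor DR5, rose by 1.18 ± 0.14 in KASUMI-1 and by 1.38 ± 0.14 in THP-1 on the log2 scale, and its ligand TNFSF10 (TRAIL) by 0.84 ± 0.20 and 0.87 ± 0.18. In KASUMI-1 the BH3-only gene BMF rose by 0.65 ± 0.19 while BAD fell by 0.66 ± 0.13 and CDKN2A by 1.01 ± 0.28. In THP-1 BCL2 fell by 0.66 ± 0.12, BID rose by 0.49 ± 0.12 and the receptor TNFRSF10A rose by 0.77 ± 0.18. Without the KASUMI-1 72 h pair the calls of TNFSF10 (0.47), BMF (0.23), BAD (-0.57) and CDKN2A (-0.52) ended there (adjusted p = 0.132 to 0.718), while TNFSF10, BMF and CDKN2A stood at 1.27, 1.09 and -1.53 without the 6 h pair. Calls also ended for BMF without either THP-1 pair (0.0628 and 0.0569) and for CDKN2A without THP-1 24 h (0.0508). In THP-1 they ended for BID (0.183 and 0.361) and TNFRSF10A (0.342 and 0.0713) without its 24 or 72 h pair, and for BCL2 without 72 h (0.135). As a list, cell death regulators were not called in KASUMI-1 (6 of 32 rose and 4 fell, 6 and 10 adjusted over the list alone, median 0.01 and mean -0.04, camera adjusted p = 0.575) or in THP-1 (4 rose and 1 fell, 5 and 3 adjusted over the list alone, camera adjusted p = 0.381). Of the glycolysis and hypoxia-inducible genes HK2 rose by 1.73 ± 0.17, PFKM by 1.15 ± 0.26 and HK1 by 0.82 ± 0.13 in THP-1, and SLC16A3, BNIP3 and PFKFB4 fell by 0.74 ± 0.18, 0.68 ± 0.14 and 0.96 ± 0.24 in KASUMI-1, where BNIP3L, a mitophagy receptor, rose by 0.95 ± 0.15. Without the KASUMI-1 72 h pair these 4 calls ended (-0.55, -0.41, -0.33 and 0.60 in this order, adjusted p = 0.0593 to 0.595), and PFKFB4 stood at -1.56 without the 6 h pair. In THP-1 the calls of PFKM (0.143 and 0.295) ended without the 24 or 72 h pair, and that of HK1 without 24 h (0.0771). The list had 2 genes higher and 8 lower of 37 in KASUMI-1, 6 and 14 adjusted over the list alone (camera adjusted p = 0.0657), and 7 higher and 2 lower in THP-1 with the same counts over the list alone (camera adjusted p = 0.208).

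Of 15 LSD1 partner genes 4 rose and 1 fell in KASUMI-1, 5 and 1 adjusted over the list alone (camera adjusted p = 0.223), with the corepressor RCOR3 up by 0.58 ± 0.14 and PHF21A by 0.44 ± 0.13. GFI1 rose and ZMYM3 fell (-0.50 ± 0.14) in THP-1 (1 and 1 over the list alone, camera adjusted p = 0.4001). Cytokine genes in KASUMI-1 gave 4 higher and 2 lower of 31, 6 and 3 over the list alone (camera adjusted p = 0.236), with CXCL8 up by 0.94 ± 0.21 and CCL5 down (-0.68 ± 0.18). ERK feedback genes there gave 4 higher and 4 lower of 31, 4 and 6 over the list alone (camera adjusted p = 0.550), with ETV1 up by 3.83 ± 0.35 and FOSL2 by 0.76 ± 0.12, and DUSP2 (-0.83 ± 0.18) and SPHK1 (-0.93 ± 0.19) down. Of 55 lysosome genes WIPI1 (0.84 ± 0.25) and TPP1 (0.48 ± 0.15) rose in KASUMI-1, neither over the list alone (camera adjusted p = 0.253), and of 72 ribosomal protein genes RPS29 fell (-0.74 ± 0.13, also over the list alone, camera adjusted p = 0.223). Erythroid and megakaryocyte genes had TAL1 lower of 12 in KASUMI-1 (-0.59 ± 0.18, also over the list alone, camera adjusted p = 0.267) and NFE2 higher in THP-1 (0.80 ± 0.15, also over the list alone, camera adjusted p = 0.884, median 0.13 and mean -0.34). Of 16 lymphoid and mast cell markers in KASUMI-1 TRAT1, a T cell adaptor with 5 vehicle and 92 LSD1i reads, rose by 3.44 ± 0.64 and CD79B (-0.70 ± 0.13) and IGLL1 fell, with the same counts over the list alone (camera adjusted p = 0.550, median 0.05 and mean 0.20 with a test leaning lower). Stem and progenitor genes in THP-1 had 3 higher and 3 lower of 25, 3 and 5 over the list alone (camera adjusted p = 0.381), with TRIB2 (2.09 ± 0.27) and HHEX (1.01 ± 0.13) up and CDK6 (-0.77 ± 0.13) and KIT down. HERPUD1 rose in THP-1 (0.75 ± 0.13) as 1 of 29 heat shock genes, also over the list alone (camera adjusted p = 0.375). Replication-dependent histones, which lack a poly(A) tail, had H2AC6 (1.38 ± 0.39) and H2BC21 (1.28 ± 0.34) higher of 15 in KASUMI-1, also over the list alone (camera adjusted p = 0.404), and 0 changed in THP-1 by edgeR's test, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.739). H2AC6 stood at 0.22 without the KASUMI-1 72 h pair (adjusted p = 0.845) and at 2.82 without the 6 h pair, H2BC21 at 0.77 (0.459) and 1.92. Both calls also ended without either THP-1 pair (0.0502 to 0.0689). Of the other KASUMI-1 calls of this paragraph, those of RCOR3 (0.35), PHF21A (0.27), TAL1 (-0.66), TRAT1 (2.01), WIPI1 (0.20), TPP1 (0.29), CXCL8 (0.61) and CCL5 (-0.30) ended without the 72 h pair (adjusted p = 0.144 to 0.813). Without the 6 h pair TRAT1 stood at 5.27, WIPI1 at 1.53, CXCL8 at 1.54, CCL5 at -1.09 and IGLL1 at -3.15, and TAL1 lost its call (0.167). PHF21A, WIPI1 and TPP1 lost theirs without either THP-1 pair (0.0501 to 0.0752), as TAL1 did without 24 h (0.0528). In THP-1 the calls of GFI1, CDK6, NFE2 and HERPUD1 ended without either pair (0.0505 to 0.451) and that of ZMYM3 without 72 h (-0.26, 0.821, and -0.78 without 24 h). There RPS29 lost its call without 24 h (0.0794) and KIT stood at -1.35 without 72 h.

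While the 11 mitochondrially encoded names had 0 reads, 8 names of 1 clone on chromosome 1 took 2.60% to 4.995% of all counts: 4.66%, 4.995%, 3.46% and 4.89% in the KASUMI-1 libraries (vehicle and LSD1i at 6 h, then at 72 h) and 2.64%, 2.60%, 2.87% and 3.70% in those of THP-1 (vehicle and LSD1i at 24 h, then at 72 h). Whether these are mitochondrial reads counted on a nuclear copy of mitochondrial sequence was not tested, so the shares are not read as expression of that clone.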
